A study of Homo sapiens with 8 samples.

How the data were processed

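RNA was measured in WI-38 human fetal lung fibroblasts in 4 states with 2 libraries each: asynchronous, quiescent, and 3 h and 6 h after serum was put back. Per the labels' protocols, cells grew in 10% serum, quiescence was induced by 72 h in 0.1% serum, RNA was extracted with RNeasy columns, and libraries were prepared with the TruSeq Stranded mRNA kit after capture on oligo-dT beads. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20, aligned with HISAT2 to GRCh38 and counted per gene with HTSeq. The deposited values were raw counts, made by the authors with those tools and not scaled further, per the labels and the whole-number values in the files. The versions of HISAT2 and HTSeq, the annotation release, the strand setting of the counting, and read length are not given in the sources used here. Whether replicates were separate cultures is not given either. All 58735 gene identifiers matched GENCODE 29, which supplied biotypes, coordinates and spans, and 58207 had a current symbol.

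Each file also held 5 rows of unassigned reads, which stayed out of library sizes and tests. They made up 18.55% to 21.961% of all rows' counts. By row, 2.877% to 3.51% were in no feature, 3.457% to 4.29% ambiguous and 2.132% to 3.917% of low alignment quality. A further 0.406% to 0.484% were not aligned and 8.616% to 10.351% not uniquely aligned. Gene counts ran from 91430572 to 109324687 per library, with 23434 to 24381 genes counted at least once, 98.309% to 98.484% of counts in protein-coding genes and 3.878% to 4.63% in mitochondrially encoded ones. At this depth the libraries of a group differed by more than counting noise (chi-square per gene 6.37 to 17.9), so precision was limited by the 2 libraries per group. Genes with a count in any library numbered 30519, and 12879 of them were too low to be tested.

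Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups (17640 genes), libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 8 libraries with 1 coefficient per group. The common biological coefficient of variation was 0.0425, with 4 residual degrees of freedom and a median of 15.2 prior ones. The contrasts were quiescent against asynchronous, 3 h and 6 h each against quiescent, and 6 h against 3 h. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its contrast, and all tests were two-sided. Standard errors were derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F. CPM used the scaled library sizes.

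The 36 gene lists, with 926 entries of which 878 were tested, were written before the data were examined. The lists share some genes, so they are not independent of each other. They were tested with camera in limma 3.58.1 on log-CPM with a prior count of 2 and a preset correlation of 0.01, which asks whether a list moved more than other genes, and adjusted over all 144 tests. As alternatives, camera was run with a correlation estimated for each list, and fry was run, which is a directional test of whether the genes of a set move one way and does not compare them with other genes. With an estimated correlation camera's test rests on the residual degrees of freedom, 4 here, and with a preset one on far more. Members were counted as called in the test of all genes, and again with the adjustment over the list alone.

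Genes to be named were set by a rule fixed in advance. It took a panel (MKI67, CCND1, CDKN1B, GAS1, FOS, EGR1, MYC, HMGCS1 and MIR222HG). It took the 5 protein-coding genes with the largest rise and the 5 with the largest fall, and 3 long non-coding genes each way. These had to be called, to have a mean of at least 10 CPM (2 for long non-coding genes) in the higher group, and to have both libraries of one group above both of the other. From each list it took up to 4 called members with the smallest p in the main direction and up to 2 in the other. A clause for every member of a list of 8 or fewer tested genes was also written but was not applied. Some genes that the rule selects are not reported here. TOP2A and CCNB1 were looked at first as markers of division.

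Temporal classes came from the calls of the 3 serum contrasts: transient (called at 3 h, then called the other way from 3 h to 6 h), progressive (the same way), late (not called at 3 h, called at 6 h and from 3 h to 6 h) and at both times. Overlaps and correlations between contrasts were set beside 20 simulations with no group effect and the overlap of independent lists. The alternatives were DESeq2 size factors, library totals, no filter, a stricter filter, the DESeq2 1.42.0 test, limma-voom, only the 2 groups compared, a replicate block, a fit without robust estimation, an adjusted p below 0.01, a change of at least 2-fold, and leaving out each library in turn. A group left with a lone library was then assumed to vary like the others. Overlaps between genes used GenomicRanges 1.54.1, and tables and plots Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

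The test was tested on simulated data of the same size in which 50 genes each were changed by 1.25, 1.5, 2 and 4-fold. For quiescent against asynchronous cells it recovered 50%, 74%, 86% and 92% of them, and 7.36% of the calls were false. For 3 h against quiescent cells the figures were 56%, 76%, 78% and 94%, with 7.32% false. For 6 h against quiescent cells they were 70%, 68%, 72% and 98%, with 9.94% false, and for 6 h against 3 h 46%, 76%, 78% and 92%, with 5.19% false. A list of 20 raised genes was found in each contrast and a list of 20 unchanged ones in none.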

Results

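RNA levels were measured by poly(A)-selected RNA sequencing in WI-38 cells, an established strain of human fetal lung fibroblasts, in 4 states of 2 libraries each. Asynchronous cells were dividing in medium with 10% serum. Quiescent cells had spent 72 h in 0.1% serum, a treatment that takes fibroblasts out of the cell cycle, and the 3 h and 6 h groups were such cells at 3 h and 6 h after 10% serum was put back. The deposited values were read counts per gene. The 2 asynchronous libraries held 109324687 and 95099078 counts in genes, the quiescent ones 91430572 and 108234187, those at 3 h 104652851 and 91837755, and those at 6 h 107235408 and 98431908. At this depth 17640 genes passed the filter on low counts, of which 13574 were protein-coding and 2791 long non-coding. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Within each group the libraries differed by more than counting noise. The chi-square per gene was 11 in asynchronous, 6.37 in quiescent, 11 in 3 h and 17.9 in 6 h cells. This does not show that the libraries are independent samples, but each was counted as 1 sample.

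Replicates lay together in the first 3 principal components, which held 63.2%, 18.2% and 9.61% of the variance. The first parted the libraries with serum put back from the other 4, and the second parted 3 h from 6 h. IGFBP5, a secreted binding protein for insulin-like growth factors, was the most abundant gene in 7 libraries and COL1A1 in the remaining asynchronous one, and the most abundant gene took 1.39% to 2.57% of the counts. Changes are given as log2 fold change ± standard error and levels as scaled CPM ± SD, with n = 2 libraries per group throughout. The largest rises and falls named are those among called protein-coding genes, and apart from them long non-coding genes, with a mean of at least 10 CPM (2 for long non-coding genes) in the higher group. Genes were located on GRCh38. The proliferation marker MKI67 (chromosome 10, 128096659 to 128126385) stood at 147 ± 14.3 CPM in asynchronous, 75.8 ± 1.47 in quiescent, 59.3 ± 6.55 in 3 h and 80.4 ± 5.75 in 6 h cells. TOP2A (chromosome 17, 40388516 to 40417950), a topoisomerase of dividing cells, went from 205 ± 0.464 to 108 ± 1.64, 78.9 ± 2.16 and 86.8 ± 2.43 CPM, and the mitotic cyclin CCNB1 (chromosome 5, 69167010 to 69178245) from 52.3 ± 1.77 to 25.1 ± 1.76, 20.5 ± 0.299 and 28.3 ± 0.461 CPM.

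**Figure D1:**
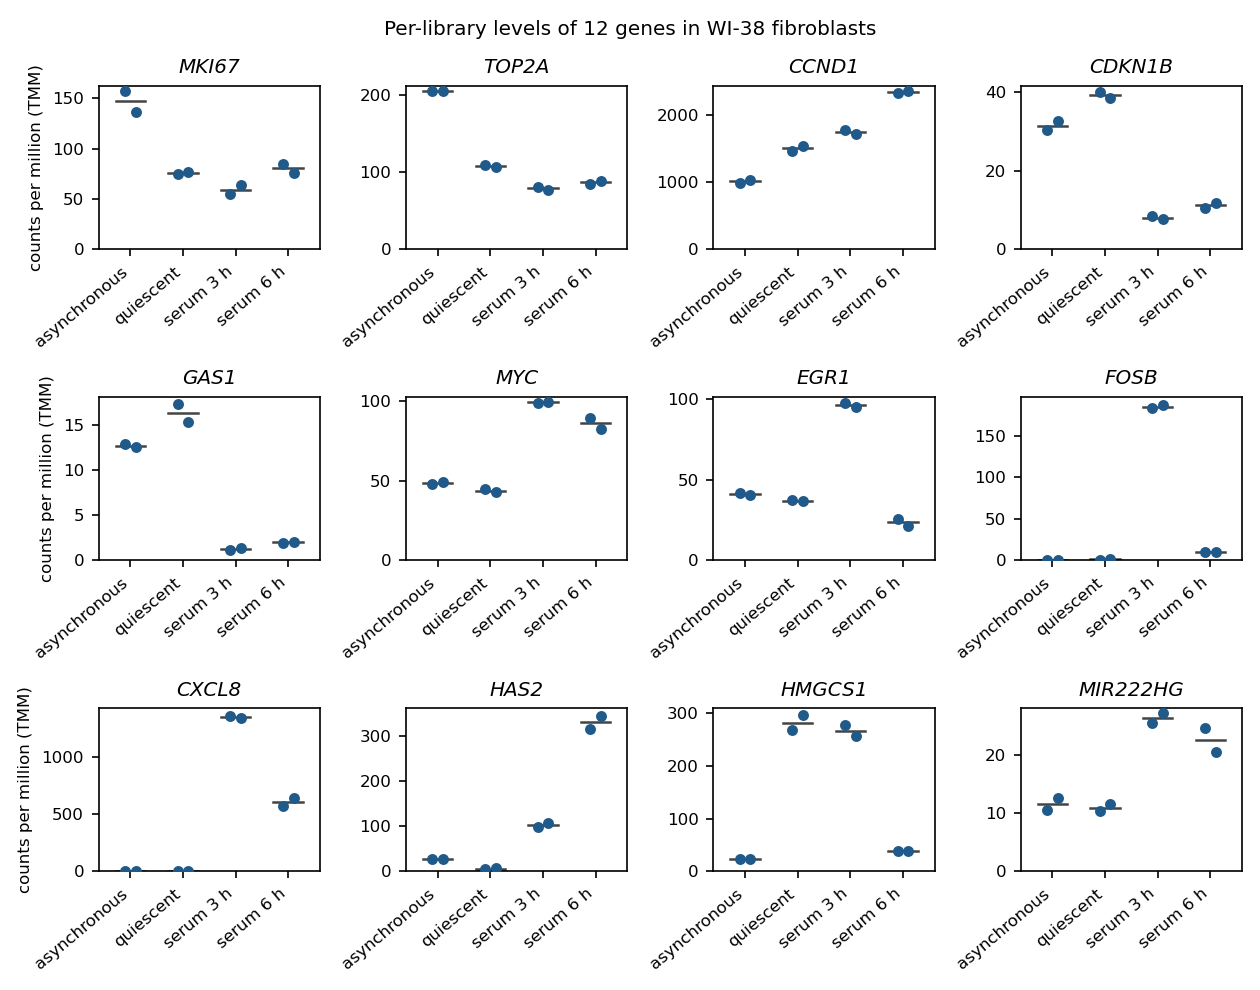
Level of 12 genes in scaled CPM (vertical axes, each from 0) in the 4 states (horizontal axes). Points are single libraries and bars the mean of 2 libraries. MKI67 and TOP2A were highest in asynchronous cells, HMGCS1 was high in quiescent and 3 h cells, and EGR1, FOSB and CXCL8 were highest at 3 h.

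The first comparison asked how serum-starved cells differed from dividing ones. Starved cells had far more mRNA for cholesterol synthesis and less for cell division. HMGCS1, which makes the precursor of mevalonate (chromosome 5, 43289395 to 43313512), was 11.9-fold higher (23.7 ± 0.0671 to 282 ± 19.9 CPM). Every one of the 47 tested DNA replication genes and 40 mitosis genes fell, MKI67 by 1.94-fold. The largest falls were in ELN, the gene of elastin (65.2 ± 4.35 to 5.07 ± 0.30 CPM, -3.69 ± 0.069), in the BMP-responsive genes ID3 (-2.75 ± 0.068) and ID1 (-2.25 ± 0.079), in the matrix protease MMP10 (-2.72 ± 0.094) and in ABCA1, which exports cholesterol from cells (-2.21 ± 0.10).

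Among the cell-cycle groups, replication genes had a median of -0.96 (camera adjusted p = 4.80e-27, and adjusted p = 0.0861 with an estimated correlation). These included TK1 at -1.48 ± 0.053, MCM5 at -1.38 ± 0.052 and MCM7 at -1.09 ± 0.048. MCM5 and MCM7 belong to the helicase that opens DNA for copying. Mitosis genes had a median of -1.0 (camera adjusted p = 6.12e-25, and adjusted p = 0.0861 with an estimated correlation). Genes included CDC20 at -1.38 ± 0.061, CCNA2 at -1.21 ± 0.053 and ANLN at -1.13 ± 0.049. Of the G1 cyclins and kinases, 4 rose, 8 fell and 2 were not called of 14 tested, with a median of -0.63 (camera adjusted p = 0.00974, and adjusted p = 0.167 with an estimated correlation). CDK2 (-1.32 ± 0.051) and CCND3 (-1.31 ± 0.053) fell while CCND1, a D-type cyclin, rose from 1010.0 ± 26.4 to 1500.5 ± 50.5 CPM (0.57 ± 0.051; chromosome 11, 69641087 to 69654474). Replication-dependent histones went the other way from the replication genes: 7 rose and 3 were not called of 10 tested, with a median of 0.65 (camera adjusted p = 0.00166, and adjusted p = 0.449 with an estimated correlation). H2AC6 rose by 1.22 ± 0.063 and H2BC21 by 0.99 ± 0.076. Some histone genes are near-identical copies, so the reads of those members are uncertain, but 17 of the 27 tested histone genes, on or off the list, shared under 5% of their 50-mers with another gene.

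Growth-arrest genes and CDK inhibitors were mostly higher: 15 rose, 2 fell and 5 were not called of 22 tested, median 0.32 (camera adjusted p = 1.91e-04, and adjusted p = 0.0861 with an estimated correlation). CDKN2B rose by 1.46 ± 0.059, GAS6 by 1.0 ± 0.052 and CCNG2 by 1.08 ± 0.06, while CDKN2C fell (-0.58 ± 0.076). CDKN1B, which encodes the inhibitor p27 (chromosome 12, 12715058 to 12722371), rose by 0.32 ± 0.062. GAS1, a gene named for growth arrest (chromosome 9, 86944363 to 86947189), rose by 0.36 ± 0.076, a call that was lost without quiescent replicate 1 (0.24, adjusted p = 0.0675, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of the FOXO target genes, 15 rose, 1 fell and 7 were not called of 23 tested, median 0.46 (camera adjusted p = 4.54e-06, and adjusted p = 0.240 with an estimated correlation). These included PIK3IP1 (1.91 ± 0.066), SESN3 (1.36 ± 0.076) and KLHL24 (1.32 ± 0.072). Of the p53 target genes, 16 rose, 1 fell and 8 were not called of 25 tested, median 0.40 (camera adjusted p = 1.41e-05, and adjusted p = 0.105 with an estimated correlation), led by TP53INP1 (1.73 ± 0.059). The ATF4 and amino acid group held PSAT1 and PHGDH, enzymes of serine synthesis, at 1.22 ± 0.049 and 0.88 ± 0.049, and 21 rose, 3 fell and 3 were not called of 27 tested, median 0.34 (camera adjusted p = 3.21e-06, and adjusted p = 0.181 with an estimated correlation). CHAC1 fell (-0.49 ± 0.054). For autophagy and lysosome genes, 17 rose, 3 fell and 11 were not called of 31 tested, median 0.16 (camera adjusted p = 0.00155, and adjusted p = 0.323 with an estimated correlation). Genes included the protease CTSK at 0.81 ± 0.056 and PSAP at 0.70 ± 0.052.

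In the sterol group, 26 rose and 1 was not called of 27 tested, and the median was 2.14 (camera adjusted p = 6.12e-25, and adjusted p = 0.130 with an estimated correlation). MSMO1 rose from 25.6 ± 0.499 to 281 ± 15.3 CPM (3.45 ± 0.057) and INSIG1, a sensor protein of the pathway, by 3.48 ± 0.062. For fatty acid synthesis, 13 rose and 3 were not called of 16 tested, with a median of 0.81 (camera adjusted p = 3.22e-09, and adjusted p = 0.152 with an estimated correlation). The desaturases SCD (2.95 ± 0.056), FADS2 (2.31 ± 0.054) and FADS1 (1.65 ± 0.05) led that group, and FABP3, a fatty acid binding protein on neither list, rose by 4.62 ± 0.14.

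Groups tied to growth and to the cytoskeleton were lower. In ribosome biogenesis, 45 fell and 2 were not called of 47 tested, with a median of -0.37 (camera adjusted p = 1.31e-14, and adjusted p = 0.288 with an estimated correlation). These included UTP20 (-0.56 ± 0.052) and NOC2L (-0.50 ± 0.047). Splicing factors had a median of -0.21, and 4 rose, 21 fell and 5 were not called of 30 tested (camera adjusted p = 0.00151, and adjusted p = 0.586 with an estimated correlation). SRSF7 fell (-0.58 ± 0.054) and the kinase CLK1 rose (0.40 ± 0.056). Glycolysis genes had a median of -0.24, and 3 rose, 14 fell and 5 were not called of 22 tested (camera adjusted p = 0.00160, and adjusted p = 0.180 with an estimated correlation). Genes included LDHA at -0.71 ± 0.055 and ALDOC at 1.12 ± 0.057. Heat-shock proteins had a median of -0.27, and 3 rose, 11 fell and 3 were not called of 17 tested (camera adjusted p = 0.0240, and adjusted p = 0.609 with an estimated correlation). Members included HSPD1 at -0.48 ± 0.059; without asynchronous replicate 2 the list was not called (adjusted p = 0.0605). The SRF/MRTF group, which codes for actin and its partners, had a median of -0.22, and 1 rose, 18 fell and 7 were not called of 26 tested (camera adjusted p = 5.45e-06, and adjusted p = 0.0861 with an estimated correlation). These included ACTB at -0.62 ± 0.055 and TPM1 at -0.67 ± 0.053. In the YAP/TEAD group, 14 fell and 10 were not called of 24 tested, median -0.17 (camera adjusted p = 3.43e-04, and adjusted p = 0.0861 with an estimated correlation). Genes included ANKRD1 at -1.54 ± 0.076. Early targets of TGF-beta and BMP had a median of -0.33, and 5 rose, 11 fell and 2 were not called of 18 tested (camera adjusted p = 0.00689, and adjusted p = 0.167 with an estimated correlation). HAS2, which makes hyaluronan, fell (-2.14 ± 0.071) and BHLHE40 rose (0.83 ± 0.058).

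The other 18 lists were not called. Members of several of them moved in both directions. Among extracellular matrix genes, 20 rose, 13 fell and 5 were not called of 38 tested (camera adjusted p = 0.269). These included COL15A1 at 2.79 ± 0.055 and DCN at 1.10 ± 0.057 against ELN and VCAN (-1.56 ± 0.053). For the NF-kB group, 7 rose, 7 fell and 13 were not called of 27 tested (camera adjusted p = 0.814). Genes included VCAM1, an adhesion receptor, at 2.05 ± 0.082 and IL11 at -1.39 ± 0.061. For proteolysis and wound-response genes, 6 rose, 9 fell and 6 were not called of 21 tested (camera adjusted p = 0.305). Members included MMP1 at -1.27 ± 0.068 and SERPINE2 at 1.11 ± 0.05. Secreted growth factors gave 11 up and 15 down (camera adjusted p = 0.544), immediate-early genes 9 up and 16 down (camera adjusted p = 0.362), ERK feedback regulators 8 up and 7 down (camera adjusted p = 0.685) and fibroblast markers 6 up and 8 down (camera adjusted p = 0.813). FOS (chromosome 14, 75278774 to 75282230) was scarce and rose from 0.779 ± 0.0418 to 1.53 ± 0.233 CPM. MYC (chromosome 8, 127735434 to 127741434) was -0.15 ± 0.051, a call lost without asynchronous replicate 2 (-0.15) or quiescent replicate 2 (-0.14). EGR1 (chromosome 5, 138465490 to 138469315) was not called at -0.16 ± 0.064 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0544), and was called lower with library totals (-0.20), with DESeq2 (-0.17), with the replicate block (-0.16) and without either 6 h library (-0.16).

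Long non-coding RNA genes had a median change of 0.078, and 306 rose and 177 fell. SNAI3-AS1 rose by 1.45 ± 0.11 and SOCS2-AS1 fell (-1.92 ± 0.18). Both overlap or neighbour a gene on the other strand, and whether the counting used strand is not stated, so they are uncertain here and in what follows for all antisense genes. MIR222HG, the host transcript of a microRNA pair that targets CDKN1B (chromosome X, 45745211 to 45770274), stood at 11.6 ± 1.37 and 11 ± 0.844 CPM (-0.077 ± 0.099, edgeR adjusted p = 0.580).

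By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3511 genes were higher and 3591 lower in quiescent cells, of which 484 and 433 by at least 2-fold, and 18 of the 36 lists were called. With library totals the split was 2957 higher and 4369 lower (40.4% higher, against 49.4%). Adjusted over the list alone, the member counts were as given except for immediate-early genes (12 up and 17 down), ERK feedback regulators (10 up and 8 down), replication-dependent histones (7 up and 1 down), fatty acid synthesis (15 up and 0 down), cytosolic ribosomal proteins (16 up and 3 down), proteolysis and wound-response genes (6 up and 10 down), interferon-stimulated genes (2 up and 1 down), secreted growth factors (11 up and 16 down), TGF-beta and BMP early target genes (5 up and 12 down), p53 target genes (17 up and 1 down), autophagy and lysosome genes (18 up and 4 down), small nucleolar RNA host genes (7 up and 7 down) and splicing factors (SR and hnRNP) (4 up and 22 down). Median, mean and test differed in sign for the immediate-early list (median -0.17, mean 0.037, test direction down), the NF-kB list (0.097, -0.013, up), microRNA host RNAs (-0.06, 0.035, down) and endothelial markers (0.15, -0.26, up), none of which was called. No list stayed called in any comparison when the correlation between its genes was estimated, even where the estimate lay below the preset 0.01. That setting also rests on only 4 residual degrees of freedom, so a lost call need not reflect correlation. Over all 144 tests, 67 were called with the preset correlation, 0 with camera's estimated one (36 had an unadjusted p under 0.05) and 106 by limma's fry.

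**Figure D2:**
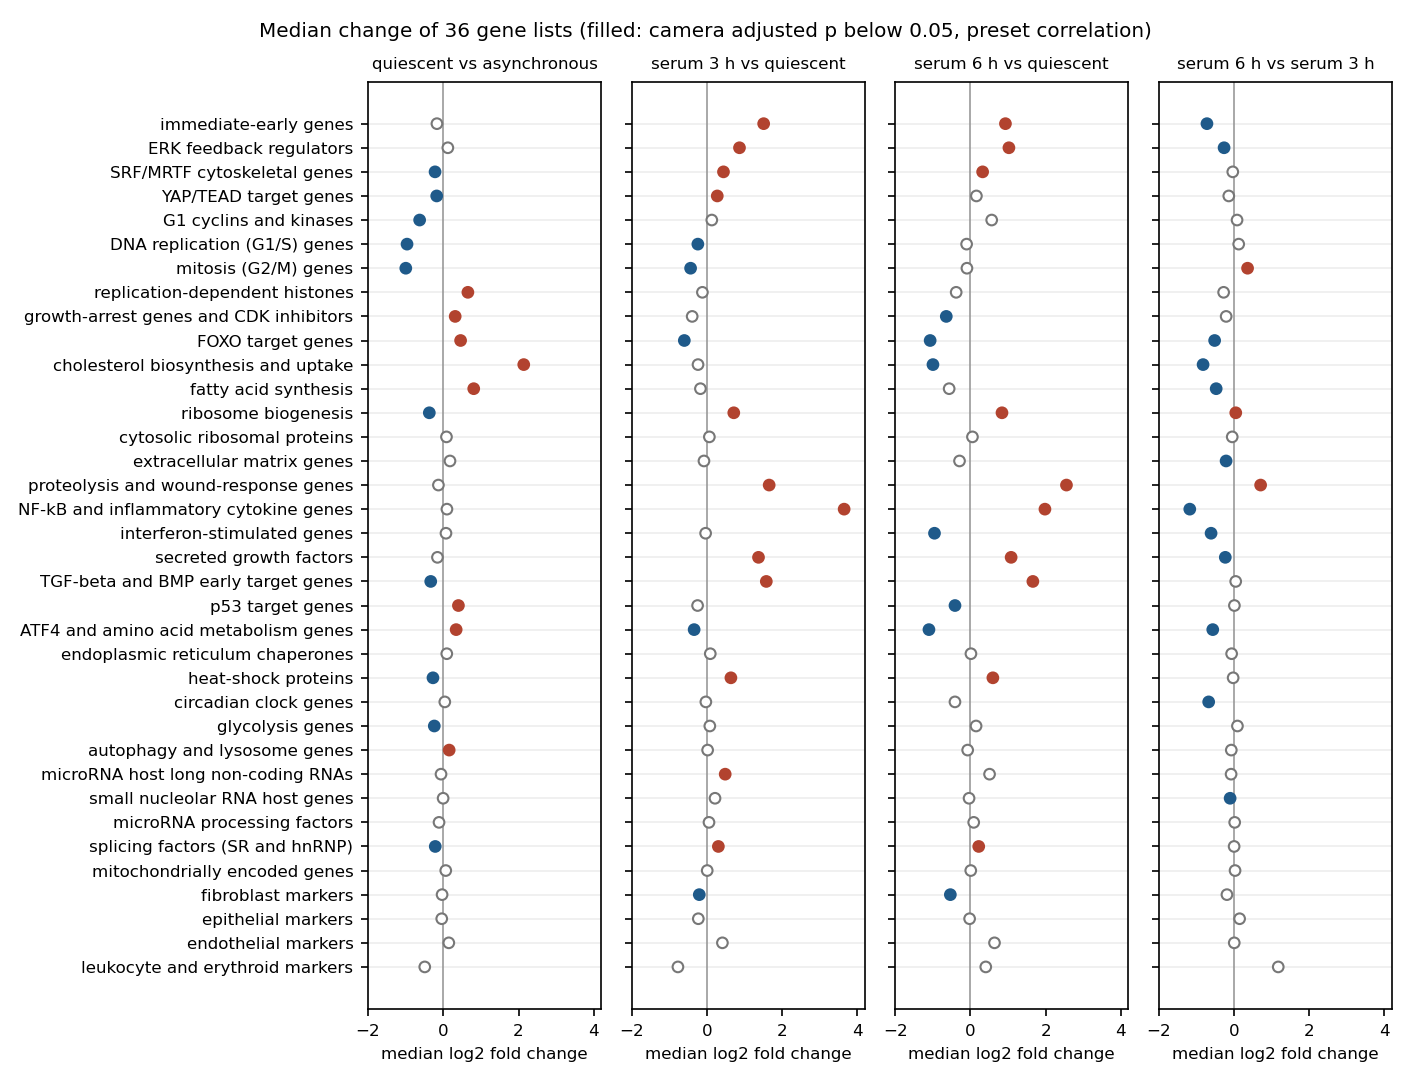
Median log2 fold change (horizontal axis) of the 36 gene lists (vertical axis) in the 4 comparisons (panels). Filled red and blue points are lists called higher and lower by camera with a preset correlation, and open points were not called. Cholesterol genes lay at 2.14 in quiescent against asynchronous cells, and NF-kB genes at 3.65 at 3 h against quiescent cells.

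The second comparison asked what 3 h of serum did to quiescent cells. Many cytokine, growth factor and immediate-early genes rose, while some fell. CXCL8, a chemokine that attracts neutrophils (chromosome 4, 73740506 to 73743716), went from 2.63 ± 0.286 to 1352 ± 12.7 CPM (9.01 ± 0.088), PTGS2, the inducible cyclooxygenase, from 0.929 ± 0.0590 to 288 ± 3.19 (8.28 ± 0.089), and FOSB, a subunit of the AP-1 transcription factor, from 1.0 ± 0.0601 to 185 ± 3.11 (7.52 ± 0.077). CXCL3 (8.14 ± 0.11) and XIRP1, an actin-binding protein (7.76 ± 0.11), were the others of the 5 largest rises among protein-coding genes. The largest falls were in TXNIP, an inhibitor of glucose uptake (105 ± 14.4 to 2.98 ± 0.282 CPM, -5.13 ± 0.10), DDIT4, an inhibitor of mTORC1 (-5.06 ± 0.085), ADAMTS15 (-4.63 ± 0.14), DEPP1 (-4.53 ± 0.14) and MN1 (-3.92 ± 0.087).

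Of the NF-kB and inflammatory cytokine genes, 25 rose and 2 fell of 27 tested, with a median of 3.65 (camera adjusted p = 9.50e-13, and adjusted p = 0.0861 with an estimated correlation). IL6 rose by 5.47 ± 0.062 and TNFAIP3, an inhibitor of NF-kB, by 5.10 ± 0.064, while IRF1 (-0.83 ± 0.064) and VCAM1 (-0.74 ± 0.079) fell. Of the immediate-early genes, 26 rose, 2 fell and 2 were not called of 30 tested, median 1.51 (camera adjusted p = 1.33e-12, and adjusted p = 0.0861 with an estimated correlation). NR4A3 rose by 5.19 ± 0.083, EGR3 by 5.78 ± 0.10 and EGR1 from 36.9 ± 0.535 to 96.0 ± 1.84 CPM (1.38 ± 0.064), whereas BTG2 fell (-1.21 ± 0.06) and FOS stayed at a low level (1.71 ± 0.0693 CPM, 0.17 ± 0.15, edgeR adjusted p = 0.343). MYC rose by 1.18 ± 0.051. ERK feedback regulators moved with them, and DUSP1, DUSP5, DUSP6 and IER3 are on both lists. Of these regulators, 16 rose, 2 fell and 2 were not called of 20 tested, median 0.87 (camera adjusted p = 9.81e-06, and adjusted p = 0.0861 with an estimated correlation). These included LIF (4.39 ± 0.056), SPRY2 (3.31 ± 0.055) and DUSP1 (3.09 ± 0.054) against ETV5 (-0.97 ± 0.056).

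Secreted growth factors had a median of 1.37, and 20 rose, 9 fell and 2 were not called of 31 tested (camera adjusted p = 2.38e-05, and adjusted p = 0.0861 with an estimated correlation). ANGPTL4 rose by 6.68 ± 0.07, the EGF-receptor ligand HBEGF by 5.58 ± 0.062, INHBA by 4.25 ± 0.063 and FGF2 by 3.32 ± 0.056, while BMP4 fell from 80.9 ± 7.36 to 9.42 ± 0.588 CPM (-3.10 ± 0.074). In the TGF-beta and BMP group, 16 rose and 2 fell of 18 tested, median 1.58 (camera adjusted p = 1.28e-07, and adjusted p = 0.0861 with an estimated correlation). These included HAS2 at 4.08 ± 0.071, ID3 at 3.58 ± 0.068 and the inhibitory SMAD7 at 3.35 ± 0.059. Proteolysis and wound-response genes had a median of 1.66, and 18 rose, 1 fell and 2 were not called of 21 tested (camera adjusted p = 1.68e-07, and adjusted p = 0.0861 with an estimated correlation). PLAUR, the urokinase receptor, rose by 1.92 ± 0.049. For SRF/MRTF cytoskeletal genes, 20 rose, 1 fell and 5 were not called of 26 tested, median 0.44 (camera adjusted p = 5.54e-06, and adjusted p = 0.0861 with an estimated correlation). Genes included CNN1 at 1.86 ± 0.053 and TPM1 at 1.18 ± 0.053. YAP/TEAD targets had a median of 0.28, and 14 rose, 6 fell and 4 were not called of 24 tested (camera adjusted p = 0.0365, and adjusted p = 0.218 with an estimated correlation). Members included ANKRD1 at 4.08 ± 0.077 and AJUBA at -1.13 ± 0.048. The YAP/TEAD list lost its call with library totals (adjusted p = 0.0705) and without quiescent replicate 2 (adjusted p = 0.0505).

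Ribosome biogenesis genes rose together: 43 rose and 4 were not called of 47 tested, with a median of 0.72 (camera adjusted p = 2.53e-13, and adjusted p = 0.307 with an estimated correlation). These included the helicase DDX21 (1.53 ± 0.054), NOP16 (1.46 ± 0.058) and RRP12 (1.30 ± 0.05). Heat-shock proteins had a median of 0.64, and 15 rose and 2 were not called of 17 tested (camera adjusted p = 6.30e-05, and adjusted p = 0.374 with an estimated correlation). Genes included HSPH1 at 1.04 ± 0.052. Splicing factors had a median of 0.31, and 20 rose, 3 fell and 7 were not called of 30 tested (camera adjusted p = 0.00368, and adjusted p = 0.616 with an estimated correlation). Members included SRSF7 at 0.73 ± 0.055 and CLK1 at -0.84 ± 0.057. Among microRNA host RNAs, 16 rose, 5 fell and 9 were not called of 30 tested, median 0.49 (camera adjusted p = 0.0443, and adjusted p = 0.550 with an estimated correlation). MIR222HG rose from 11 ± 0.844 to 26.5 ± 1.22 CPM (1.27 ± 0.096), MIR31HG by 2.53 ± 0.097 and MIR22HG by 1.29 ± 0.049, while MIR503HG fell (-1.36 ± 0.077). The microRNA host list was not called without quiescent replicate 1 (adjusted p = 0.0519), 3 h replicate 2 (0.0684), 6 h replicate 1 (0.0561) or 6 h replicate 2 (0.0554).

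Mitosis genes, already lower in quiescent than in asynchronous cells but still expressed, were lower again: 1 rose, 33 fell and 6 were not called of 40 tested, with a median of -0.43 (camera adjusted p = 1.21e-07, and adjusted p = 0.0861 with an estimated correlation). AURKA fell from 41.5 ± 0.630 to 20.3 ± 0.587 CPM (-1.03 ± 0.054), and KIF20A (-0.93 ± 0.067) and MKI67 (-0.35 ± 0.08, and -0.55 with library totals) fell with it. For DNA replication genes, 3 rose, 29 fell and 15 were not called of 47 tested, median -0.24 (camera adjusted p = 0.00116, and adjusted p = 0.469 with an estimated correlation). These included MCM2 at -0.64 ± 0.065 and RRM2 at 0.43 ± 0.058 (0.24 with library totals). FOXO target genes had a median of -0.60, and 4 rose, 17 fell and 2 were not called of 23 tested (camera adjusted p = 0.00212, and adjusted p = 0.384 with an estimated correlation); next to TXNIP, CCNG2 (-1.72 ± 0.063) and KLHL24 (-1.81 ± 0.077) fell, and BCL6 rose (1.39 ± 0.055). In the ATF4 and amino acid group, 4 rose, 20 fell and 3 were not called of 27 tested, median -0.34 (camera adjusted p = 7.80e-04, and adjusted p = 0.307 with an estimated correlation). Genes included STC2 at -1.04 ± 0.051 and CEBPB at 1.42 ± 0.056. Fibroblast markers had a median of -0.20, and 1 rose, 9 fell and 6 were not called of 16 tested (camera adjusted p = 0.0297, and adjusted p = 0.384 with an estimated correlation). FOXF1 (-0.94 ± 0.051), PDGFRA (-0.59 ± 0.056) and COL3A1 (-0.53 ± 0.055) fell and VIM rose (0.44 ± 0.05, and 0.25 with library totals); the 3 collagens on this list are also on the extracellular matrix list.

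Several lists were not called but held strong single changes. CDKN1B fell from 39.2 ± 1.0 to 7.99 ± 0.516 CPM (-2.29 ± 0.07) and GAS1 from 16.2 ± 1.41 to 1.28 ± 0.191 (-3.67 ± 0.10), on the growth-arrest list, of which 6 rose, 13 fell and 3 were not called of 22 tested (camera adjusted p = 0.0593). In the p53 group, 8 rose, 15 fell and 2 were not called of 25 tested (camera adjusted p = 0.147). These included TP53INP1 at -2.59 ± 0.063 and GDF15 at 1.30 ± 0.052. The sterol list had a median of -0.23 and was not called (camera adjusted p = 0.108). Of it, 5 rose, 17 fell and 5 were not called of 27 tested, with MVK at -1.40 ± 0.062 and INSIG1 at 1.24 ± 0.055. HMGCS1 was -0.079 ± 0.054 (edgeR adjusted p = 0.223), and was called lower with library totals (-0.28). Fatty acid genes (camera adjusted p = 0.512), G1 cyclins and kinases (camera adjusted p = 0.326) and glycolysis genes (camera adjusted p = 0.228) were not called as lists either. ODC1, the first enzyme of polyamine synthesis, rose by 1.76 ± 0.058, and PFKFB3, an activator of glycolysis, by 2.25 ± 0.048. CCND1 rose by 0.22 ± 0.051 and was not called with library totals (0.019, adjusted p = 0.743). In extracellular matrix, 10 rose, 7 fell and 21 were not called of 38 tested (camera adjusted p = 0.896). Genes included ELN at 2.54 ± 0.07 and TNC at 1.44 ± 0.058. Cytosolic ribosomal proteins changed little: 13 rose and 62 were not called of 75 tested, median 0.067 (camera adjusted p = 0.0794), and RPS16 (0.18 ± 0.061) changed sign with library totals (-0.015, adjusted p = 0.846) and was not called without quiescent replicate 1 (0.18), quiescent replicate 2 (0.16) or 3 h replicate 2 (0.12). Ribosomal protein genes have many near copies, so RPS16 is uncertain.

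Other-cell markers were near the floor apart from a few. Of 6 tested epithelial markers 2 rose and 1 fell (camera adjusted p = 0.761), and the tight-junction gene CLDN4 went from 0.280 ± 0.0611 to 17.5 ± 0.172 CPM (5.98 ± 0.12). Of 6 endothelial markers 2 rose and 1 fell (camera adjusted p = 0.767), and VWF stood at 2.51 ± 0.360 CPM. Of 3 leukocyte and erythroid markers none was called (camera adjusted p = 0.835). Among long non-coding genes 531 rose and 601 fell, with a median of -0.12. ENSG00000227619, an intergenic RNA gene without a symbol (chromosome 9, 129575409 to 129584556), rose the most (6.93 ± 0.085), followed by LINC00862 (5.87 ± 0.19) and LINC00161 (5.84 ± 0.15), and ENSG00000259807 fell the most (-3.04 ± 0.11).

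At 3 h, 5078 genes were higher and 5140 lower than in quiescent cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), of which 1554 and 1078 by at least 2-fold, and 17 lists were called. Adjusted over the list alone, the member counts were as given except for immediate-early genes (27 up and 2 down), YAP/TEAD target genes (15 up and 6 down), mitosis (G2/M) genes (1 up and 35 down), replication-dependent histones (0 up and 3 down), cytosolic ribosomal proteins (3 up and 0 down), extracellular matrix genes (9 up and 6 down), secreted growth factors (21 up and 9 down), p53 target genes (9 up and 15 down), endoplasmic reticulum chaperones (4 up and 1 down) and microRNA host long non-coding RNAs (16 up and 6 down). Median and mean differed in sign, with the test following the mean, for extracellular matrix genes (-0.076 and 0.085), circadian clock genes (-0.026 and 0.04) and epithelial markers (-0.23 and 0.91). Scaling to library totals instead of TMM moved the median of all genes by -0.20, and the split was then 3560 higher and 8145 lower (30.4% higher, against 49.7%), so the changes here are relative to the TMM-scaled bulk of genes.

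The third comparison set 6 h of serum against quiescent cells. The mRNAs of sterol genes had dropped, many cytokine genes were still far above quiescent cells, and more genes had risen. HMGCS1 fell from 282 ± 19.9 to 38.2 ± 0.712 CPM (-2.88 ± 0.059), with all 27 sterol genes lower. CXCL8 stood at 607 ± 48.7 CPM (7.86 ± 0.085). IL33, a cytokine of the IL-1 family (7.78 ± 0.15), THBD, the thrombin receptor thrombomodulin (7.78 ± 0.19), ESM1 (7.70 ± 0.11) and CLDN4 (7.58 ± 0.11) rose from under 1 CPM. The growth factor genes FGF9 (-5.93 ± 0.13) and GDF5 (-4.90 ± 0.083), the receptor gene KIT (-4.47 ± 0.10), ARHGAP28 (-5.43 ± 0.14) and DEPP1 (-4.41 ± 0.13) fell the most.

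In the sterol list all 27 tested members fell, with a median of -1.0 (camera adjusted p = 1.89e-10, and adjusted p = 0.261 with an estimated correlation). These included MVK (-3.12 ± 0.071). ATF4 and amino acid genes had a median of -1.10, and 2 rose, 21 fell and 4 were not called of 27 tested (camera adjusted p = 2.70e-07, and adjusted p = 0.167 with an estimated correlation). Genes included DDIT4 at -3.28 ± 0.07 and PSPH at -2.38 ± 0.059. Of the FOXO target genes, 2 rose, 17 fell and 4 were not called of 23 tested, median -1.07 (camera adjusted p = 3.64e-05, and adjusted p = 0.277 with an estimated correlation). Members included CCNG2 at -3.53 ± 0.073 and PIK3R1 at 1.12 ± 0.055. Growth-arrest genes and CDK inhibitors had a median of -0.64, and 4 rose, 14 fell and 4 were not called of 22 tested (camera adjusted p = 0.00527, and adjusted p = 0.145 with an estimated correlation). CDKN2B (-2.27 ± 0.063), GAS1 (-3.01 ± 0.096) and CDKN1B (-1.80 ± 0.067) fell, while RB1 rose (0.56 ± 0.049). In the p53 group, 7 rose, 17 fell and 1 was not called of 25 tested, median -0.41 (camera adjusted p = 0.0173, and adjusted p = 0.269 with an estimated correlation). These included PLK2 at -1.81 ± 0.054 and PLK3 at 1.46 ± 0.06. Interferon-stimulated genes had a median of -0.95, and 1 rose, 12 fell and 8 were not called of 21 tested (camera adjusted p = 0.0110, and adjusted p = 0.622 with an estimated correlation). Genes included IFIT2 at -3.65 ± 0.16 and STAT2 at -0.95 ± 0.052. Fibroblast markers had a median of -0.53, and 3 rose, 10 fell and 3 were not called of 16 tested (camera adjusted p = 0.0298, and adjusted p = 0.384 with an estimated correlation). Members included PDGFRA at -1.36 ± 0.057 and TWIST2 at 0.61 ± 0.068.

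Proteolysis and wound-response genes had the highest median of the lists called higher, 2.55, and 17 rose, 2 fell and 2 were not called of 21 tested (camera adjusted p = 1.15e-06, and adjusted p = 0.0861 with an estimated correlation). HAS2 rose from 6.04 ± 0.593 to 329 ± 20.7 CPM (5.76 ± 0.074) and TIMP3, an inhibitor of matrix proteases, by 3.14 ± 0.055, while ADAMTS5 fell (-2.83 ± 0.073). In the NF-kB group, 22 rose, 3 fell and 2 were not called of 27 tested, median 1.98 (camera adjusted p = 7.91e-07, and adjusted p = 0.0861 with an estimated correlation). These included IL11 at 5.23 ± 0.071 and VCAM1 at -3.55 ± 0.091. Early TGF-beta and BMP targets had a median of 1.66, and 15 rose and 3 fell of 18 tested (camera adjusted p = 2.67e-05, and adjusted p = 0.0861 with an estimated correlation). Genes included ID1 at 5.41 ± 0.078, ID3 at 5.27 ± 0.07 and BAMBI at -1.01 ± 0.06. Secreted growth factors had a median of 1.08, and 19 rose, 10 fell and 2 were not called of 31 tested (camera adjusted p = 0.0103, and adjusted p = 0.180 with an estimated correlation). Members included NRG1 at 3.06 ± 0.054 and BMP4 at -4.37 ± 0.082. Immediate-early genes had a median of 0.93, and 25 rose, 4 fell and 1 was not called of 30 tested (camera adjusted p = 3.85e-06, and adjusted p = 0.0861 with an estimated correlation). These included NR4A1 at 3.75 ± 0.064 and MYC at 0.97 ± 0.051 but ATF3 at -2.51 ± 0.076 and EGR1 at -0.65 ± 0.066. FOS reached 1.96 ± 0.119 CPM (0.37 ± 0.14), a call lost with library totals (0.24), with DESeq2 (0.38), and without quiescent replicate 2 (0.22) or 6 h replicate 2 (0.31). ERK feedback regulators had a median of 1.02, and 13 rose, 5 fell and 2 were not called of 20 tested (camera adjusted p = 0.00335, and adjusted p = 0.140 with an estimated correlation). Genes included SPRY4 at 2.95 ± 0.065 and SPRY1 at -2.40 ± 0.10.

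Ribosome biogenesis genes stayed raised: 45 rose and 2 were not called of 47 tested, median 0.84 (camera adjusted p = 9.52e-14, and adjusted p = 0.306 with an estimated correlation). These included RRP12 at 1.68 ± 0.05 and UTP20 at 1.31 ± 0.052. SRF/MRTF genes had a median of 0.32, and 16 rose, 4 fell and 6 were not called of 26 tested (camera adjusted p = 0.00584, and adjusted p = 0.145 with an estimated correlation). Genes included PDLIM5 at 1.98 ± 0.047 and LMOD1 at -1.33 ± 0.052. Heat-shock proteins had a median of 0.60, and 14 rose, 1 fell and 2 were not called of 17 tested (camera adjusted p = 7.57e-04, and adjusted p = 0.432 with an estimated correlation). Members included HSPA8 at 0.82 ± 0.055. Splicing factors had a median of 0.22, and 20 rose, 6 fell and 4 were not called of 30 tested (camera adjusted p = 0.0363, and adjusted p = 0.728 with an estimated correlation). These included PTBP1 at 0.54 ± 0.046; this call was lost with library totals (adjusted p = 0.0915) and without 6 h replicate 2 (adjusted p = 0.0776). Among lists not called were mitosis genes, with 6 up and 16 down (camera adjusted p = 0.147), replication genes, with 8 up and 20 down (camera adjusted p = 0.130), and histones, with 0 up and 5 down (camera adjusted p = 0.0875). MKI67 stood at 0.086 ± 0.08 against quiescent cells (edgeR adjusted p = 0.366). G1 cyclins and kinases had 9 up and 4 down (camera adjusted p = 0.108). Genes included CDK2 at 0.78 ± 0.051 and CCND1 at 0.64 ± 0.051 against SKP2 at -1.58 ± 0.056. Glycolysis had 12 up and 6 down (camera adjusted p = 0.111). Members included HK2 at 1.66 ± 0.051 and the glucose transporter SLC2A1 at -1.40 ± 0.053. Fatty acid genes (camera adjusted p = 0.0802), extracellular matrix genes (camera adjusted p = 0.0738), YAP/TEAD targets (camera adjusted p = 0.362), microRNA host RNAs (camera adjusted p = 0.0618) and endothelial markers (camera adjusted p = 0.862) were not called either. COL3A1, a main fibrillar collagen, fell (-1.16 ± 0.056), as did SCD (-1.29 ± 0.052) and TGFB2 (-2.17 ± 0.058), and MIR222HG rose by 1.04 ± 0.096.

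Of the long non-coding genes 488 rose and 776 fell at 6 h, with a median of -0.22, against -0.0021 for all protein-coding genes and -0.17 for those matched on expression (difference from the latter -0.049, interval -0.10 to 0.0061). ENSG00000227619 (6.46 ± 0.085) and LINC00862 (6.06 ± 0.18) rose, LINC00900 (-3.77 ± 0.20) fell, and SBF2-AS1, an antisense gene and so uncertain, was -3.21 ± 0.074. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 5643 genes were higher and 5746 lower at 6 h than in quiescent cells, of which 1578 and 1699 by at least 2-fold, and 17 lists were called. Adjusted over the list alone, the member counts were as given except for cytosolic ribosomal proteins (5 up and 0 down), p53 target genes (7 up and 18 down), endoplasmic reticulum chaperones (7 up and 6 down), glycolysis genes (13 up and 6 down) and autophagy and lysosome genes (10 up and 11 down). Signs differed for endoplasmic reticulum chaperones (median 0.014, camera up, fry down), mitochondrially encoded genes (0.0093, up, fry down), autophagy and lysosome genes (median -0.073, mean 0.075, camera down, fry up), small nucleolar RNA host genes (-0.036, 0.14, up) and epithelial markers (-0.021, 1.30, up), none of them called. Library totals moved the median of all genes by -0.13, and gave 4524 higher and 7276 lower (38.3% higher, against 49.5%).

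The direct contrast of 6 h with 3 h, in which quiescent cells are on neither side, showed how the response moved on. Most immediate-early genes had fallen back and most sterol genes were lower, while most mitosis genes and 13 of 21 proteolysis and wound-response genes were higher. FOSB fell from 185 ± 3.11 to 10.2 ± 0.429 CPM (-4.18 ± 0.058), EGR1 from 96.0 ± 1.84 to 23.5 ± 2.99 (-2.03 ± 0.066), and CXCL3 (-4.34 ± 0.077), RRAD (-4.28 ± 0.066), ATF3 (-4.27 ± 0.073) and EGR3 (-4.19 ± 0.088) fell at least as steeply as FOSB. The largest rises among protein-coding genes were in PODXL, a sialomucin of the cell surface (13.4 ± 0.0828 to 152 ± 0.962 CPM, 3.50 ± 0.064), the potassium channel gene KCNQ5 (3.31 ± 0.091), ADPRHL1 (3.31 ± 0.11), RASD2 (3.29 ± 0.11) and GABBR2 (2.96 ± 0.07).

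Immediate-early genes had a median of -0.72, and 4 rose, 22 fell and 4 were not called of 30 tested (camera adjusted p = 1.18e-06, and adjusted p = 0.0861 with an estimated correlation). These included NR4A3 at -2.77 ± 0.067, MYC at -0.21 ± 0.05 and NR4A1 at 0.82 ± 0.055. In the NF-kB group, 2 rose, 22 fell and 3 were not called of 27 tested, median -1.17 (camera adjusted p = 1.93e-08, and adjusted p = 0.0861 with an estimated correlation). Genes included NFKB1 at -2.40 ± 0.049, TNFAIP3 at -2.16 ± 0.053 and IL33 at 2.43 ± 0.084. ERK feedback regulators had a median of -0.26, and 3 rose, 11 fell and 6 were not called of 20 tested (camera adjusted p = 0.00751, and adjusted p = 0.159 with an estimated correlation). Members included LIF at -2.41 ± 0.051 and EPHA4 at 0.64 ± 0.049. Secreted growth factors had a median of -0.23, and 6 rose, 17 fell and 8 were not called of 31 tested (camera adjusted p = 0.00693, and adjusted p = 0.167 with an estimated correlation). These included HBEGF at -1.66 ± 0.051 and AREG at 1.22 ± 0.085. Proteolysis and wound-response genes were higher at a median of 0.71, and 13 rose, 4 fell and 4 were not called of 21 tested (camera adjusted p = 0.00948, and adjusted p = 0.258 with an estimated correlation). MMP1, a collagenase, rose from 281 ± 25.3 to 839 ± 54.7 CPM (1.58 ± 0.068), and PTGS2 fell (-1.49 ± 0.056). Mitosis genes had a median of 0.36, and 31 rose and 9 were not called of 40 tested (camera adjusted p = 1.45e-07, and adjusted p = 0.0861 with an estimated correlation). Genes included CENPE at 0.87 ± 0.054, CDC20 at 0.74 ± 0.065 and MKI67 at 0.44 ± 0.08.

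Sterol genes were lower at a median of -0.82, and 25 fell and 2 were not called of 27 tested (camera adjusted p = 1.33e-12, and adjusted p = 0.221 with an estimated correlation). These included INSIG1 at -2.21 ± 0.057 and HMGCS1 at -2.80 ± 0.059. Fatty acid synthesis had a median of -0.47, and 2 rose, 12 fell and 2 were not called of 16 tested (camera adjusted p = 0.00212, and adjusted p = 0.384 with an estimated correlation). Genes included SCD at -0.95 ± 0.052. In the ATF4 and amino acid group, 2 rose, 22 fell and 3 were not called of 27 tested, median -0.56 (camera adjusted p = 1.25e-06, and adjusted p = 0.178 with an estimated correlation). Members included the cystine transporter gene SLC7A11 at -1.50 ± 0.054 and DDIT4 at 1.78 ± 0.10. FOXO target genes had a median of -0.51, and 5 rose, 16 fell and 2 were not called of 23 tested (camera adjusted p = 0.00404, and adjusted p = 0.417 with an estimated correlation). These included GADD45A at -1.83 ± 0.05 and IRS2 at 1.05 ± 0.058. Extracellular matrix genes had a median of -0.21, and 3 rose, 23 fell and 12 were not called of 38 tested (camera adjusted p = 0.00530, and adjusted p = 0.655 with an estimated correlation). Genes included THBS1 at -1.17 ± 0.052, COL3A1 at -0.64 ± 0.056 and ELN at 1.04 ± 0.058. Ribosome biogenesis genes were only just called, at a median of 0.048, and 18 rose, 8 fell and 21 were not called of 47 tested (camera adjusted p = 0.0493, and adjusted p = 0.779 with an estimated correlation). Members included POLR1A at 0.59 ± 0.051 and WDR43 at -0.27 ± 0.048; the call was lost with the replicate block (adjusted p = 0.0551), without 3 h replicate 2 (0.138) and without 6 h replicate 2 (0.265).

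Lists not called in this contrast included DNA replication, where 21 members rose and 8 fell (camera adjusted p = 0.0593), and TGF-beta and BMP targets, where 7 rose and 8 fell (camera adjusted p = 0.840). Of the latter, ID3 rose further (1.69 ± 0.057) and TSC22D1 fell (-1.38 ± 0.048). Others were growth-arrest genes (camera adjusted p = 0.185), p53 targets (camera adjusted p = 0.659), G1 cyclins and kinases (camera adjusted p = 0.102), histones (camera adjusted p = 0.216), SRF/MRTF genes (camera adjusted p = 0.207), YAP/TEAD targets (camera adjusted p = 0.796), heat-shock proteins (camera adjusted p = 0.896), splicing factors (camera adjusted p = 0.896), fibroblast markers (camera adjusted p = 0.130), glycolysis genes (camera adjusted p = 0.352), lysosome genes (camera adjusted p = 0.326) and microRNA host RNAs (camera adjusted p = 0.816). CCND1 rose further (0.42 ± 0.051), while CDKN1B (0.49 ± 0.074) and GAS1 (0.66 ± 0.13) recovered in part. MIR222HG was -0.22 ± 0.091 (edgeR adjusted p = 0.0564), and was called lower without 6 h replicate 1 (-0.37, adjusted p = 0.0011). FOS was 0.20 ± 0.14 (edgeR adjusted p = 0.270). Of long non-coding genes 293 rose and 475 fell, among them LINC00707 (3.68 ± 0.19) and KIF23-AS1, an antisense gene and so uncertain (-2.79 ± 0.094).

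Between 3 h and 6 h, 4227 genes rose and 4487 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), of which 695 and 937 by at least 2-fold, and 15 lists were called. Adjusted over the list alone, the member counts were as given except for immediate-early genes (4 up and 23 down), ERK feedback regulators (3 up and 12 down), SRF/MRTF cytoskeletal genes (4 up and 10 down), YAP/TEAD target genes (11 up and 13 down), cytosolic ribosomal proteins (0 up and 0 down), extracellular matrix genes (3 up and 24 down), TGF-beta and BMP early target genes (8 up and 8 down), p53 target genes (7 up and 9 down), endoplasmic reticulum chaperones (2 up and 4 down), splicing factors (SR and hnRNP) (6 up and 7 down) and leukocyte and erythroid markers (3 up and 0 down). Signs differed for TGF-beta and BMP targets (median 0.046, camera up, fry down), p53 targets (median 0.011, mean -0.16, down), glycolysis genes (0.092, -0.0063, camera up, fry down), microRNA processing factors (0.019, -0.016, up), splicing factors (0.0039, -0.045, down), mitochondrially encoded genes (0.029, -0.0058, camera up, fry down) and endothelial markers (median 0.0073, mean 0.031, down). With library totals the split was 5209 higher and 3652 lower (58.8% higher, against 48.5%).

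**Figure D3:**
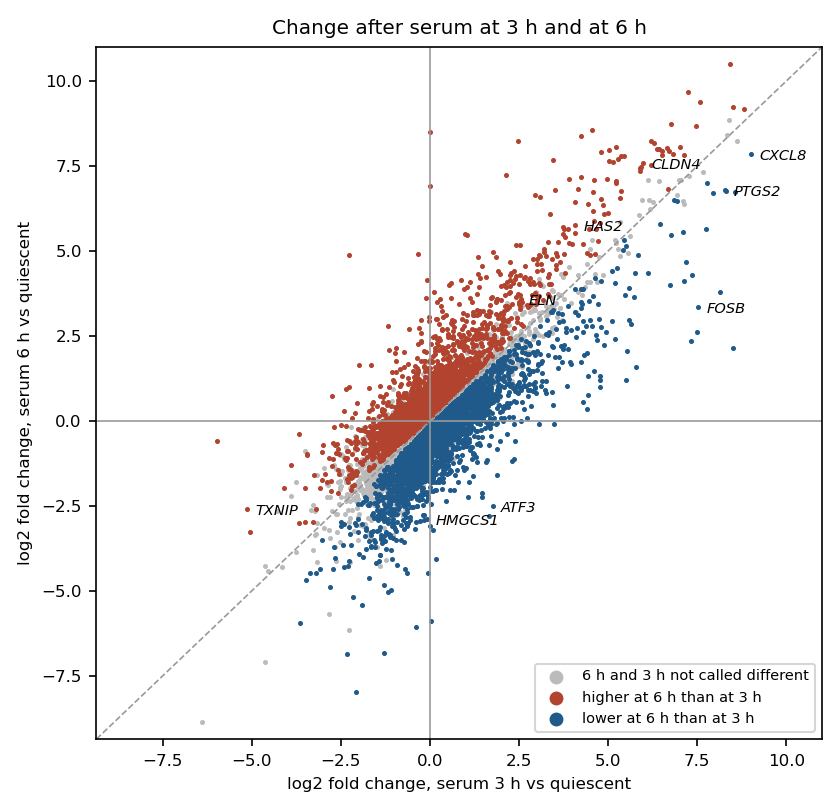
Log2 fold change against quiescent cells at 3 h (horizontal axis) and at 6 h (vertical axis) of serum for the 17640 genes tested. Each point is a gene, red where it was higher at 6 h than at 3 h (4227), blue where it was lower (4487) and grey where it was not called, and the dashed line marks equal change. Both axes share the quiescent libraries. FOSB lies far below the line and CLDN4 above it.

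The calls of the 3 serum contrasts sorted genes into temporal classes. Transient rises, up at 3 h and then down from 3 h to 6 h, numbered 1763 (1215 with library totals). At 6 h, 919 of them were still above quiescent cells and 243 were below. Transient falls numbered 1627 (2836 with library totals), of which 577 were still below quiescent cells at 6 h and 311 were above. Genes that rose at 3 h and rose further numbered 1376 (1100 with library totals), and genes that fell further 1455 (1744 with library totals). A rise called only by 6 h was seen for 1029 genes and a late fall for 1088 (576 with library totals), while 1666 were up and 1726 down at both times without a called difference between them. Of the NF-kB list 20 of 27 members were transient rises, and of the immediate-early list 21 of 30. A transient rise need not be a full return: at 6 h, 22 members of the NF-kB list and 25 of the immediate-early list were called above quiescent cells. Of the mitosis list 30 of 40 were transient falls, and 15 of 27 sterol genes fell progressively. Independent lists of the same sizes would have given 1292 transient rises, 1232 transient falls, 1217 progressive rises and 1307 progressive falls. The 3 h libraries enter both contrasts with opposite sign, so part of the excess of transient classes may come from them. Such sharing works against progressive calls and so does not account for their excess. The independent lists also treat all genes as equally likely to be called. At 3 h 63.9% of protein-coding and 40.6% of long non-coding genes were called, and from 3 h to 6 h 56.4% and 27.5%. That difference alone raises the overlaps above those of independent lists, so the excess is not evidence of an effect.

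The last question was whether serum undid the changes of starvation. Of 484 genes that were at least 2-fold higher in quiescent cells, 217 were called lower again at 3 h and 320 at 6 h, while 61 and 53 rose further. Of 433 genes at least 2-fold lower, 165 and 209 rose again and 75 and 65 fell further. HMGCS1, INSIG1 and MSMO1 were among the genes raised by starvation, and ELN, ID1 and ID3 among those that fell. Over all calls, 2156 of the 3511 genes raised by starvation were lower at 6 h, where independent lists would share 1144, and 1996 of the 3591 lowered ones were higher, against 1149. At 3 h these overlaps were 1650 against 1023 and 1577 against 1034. Simulated groups with no effect shared at most 2 genes, but they had at most 7 calls, too few to judge by. Part of these overlaps may come from the shared quiescent libraries, and part from genes that are easier to call in every contrast. In the contrast of 6 h with 3 h, where no library of the starvation change is on either side, 1673 of the raised genes fell, against 893 for independent lists, and 1467 of the lowered ones rose, against 860.5. Of the genes changed at least 2-fold by starvation, 251 raised ones fell from 3 h to 6 h and 39 rose, and 161 lowered ones rose and 57 fell. Across the 17640 genes, which are not independent replicates, the starvation change correlated with the change at 3 h at r = -0.224 and at 6 h at r = -0.325. The quiescent libraries enter both sides with opposite sign, and simulation with no effect gave r = -0.487 and -0.502. The covariances were -0.125 and -0.208 against simulated values of -0.027 each, a difference of -0.098 and -0.18. With quiescent replicate 1 on one side and replicate 2 on the other, r was -0.16 and -0.277, and each side then rested on a single quiescent library. Against the 6 h to 3 h contrast r was -0.213, where simulation gave -0.0012. The 3 h and 6 h changes correlated at r = 0.798, with a simulated 0.476, so part of this correlation may come from the shared quiescent libraries. Their covariance was 0.9 against a simulated 0.027, a difference of 0.873. The groups hold 2 libraries each, too few to split the controls into sets of 2.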

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

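These results stand out because the responses at 3 h and 6 h differed, as tested by the direct contrast between them. It called 8714 genes, 49.4% of those tested. Of 279 genes that the naming rule picked in the comparisons of 3 h and 6 h with quiescent cells, 214 were called. The rule favoured large changes in these same 3 h and 6 h libraries, so a high share was built in. Median log2 changes from 3 h to 6 h were negative for NF-kB (-1.17), cholesterol (-0.82), immediate-early (-0.72), circadian clock (-0.67), interferon-stimulated (-0.61), ATF4 (-0.56), FOXO target (-0.51), fatty acid (-0.47), ERK feedback (-0.26), growth factor (-0.23), extracellular matrix (-0.21) and small nucleolar RNA host genes (-0.10). They were positive for proteolysis (0.71), mitosis (0.36) and ribosome biogenesis genes (0.048). All 15 lists lost their call with an estimated correlation. Ribosome biogenesis lost it also with the replicate block (adjusted p = 0.0551) and without replicate 2 at 3 h (0.138) or 6 h (0.265), interferon-stimulated genes without 3 h replicate 1 (0.0541), and small nucleolar RNA host genes with library totals (0.106) and when any 1 of 4 libraries was left out. Of the panel of 9 genes, 7 were called: MKI67 (0.44), CCND1 (0.42), CDKN1B (0.49), GAS1 (0.66), EGR1 (-2.03), MYC (-0.21) and HMGCS1 (-2.80). Against quiescent cells, 243 genes were up at 3 h and down at 6 h, and 311 were down at 3 h and up at 6 h.

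The tests of scaling for mitosis genes and of S phase were chosen only after their result was seen, and the test of shared histone reads was added after the histone rise was known, with its own outcome unseen. The resampled differences between long non-coding and matched coding genes were also added after those results were known. The verdict on low expression was changed after its result was first seen, as described below, and the values printed for the matched sets were chosen then.

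Mitosis genes were lower at 3 h than in quiescent cells (median -0.43). An error in scaling is 1 factor per library and moves all genes alike, but 95% of 10000 expression-matched random lists had medians from -0.18 to 0.12, and 0 were as low, which restates the call of the list but leaves other genes nearly unmoved. After a trend on GC content, exon length and mean expression was removed the median was -0.42 (interval -0.56 to -0.33), and both 3 h libraries had most members below both quiescent ones (90% and 87.5%). These values argue against GC content, length and a single library as the whole cause, and a scaling factor alone would not set the list apart. TMM places the bulk of genes near 0 by construction, so the fall is relative to that bulk, and mRNA per cell was not measured. Whether mitosis mRNA fell per cell at all, and whether fewer cells were cycling, was not tested.

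Replication-dependent histone genes were higher in quiescent than in asynchronous cells (median 0.65). The 17 tested histone genes not on the list had a median of 0.31 (0.16 to 0.97), with 6 up, 0 down and 11 not called. That interval lies above 0, though it spans the 0.3 set beforehand as the mark against a choice of genes. The 17 histone genes with under 5% of shared 50-mers had a median of 0.42 (0.16 to 1.01), with 8 up. These values argue against the choice of genes and against shared reads as the whole cause. A larger share of cells in S phase is argued against by the 47 DNA replication genes that fell. Summed histone CPM rose 1.80 times in these poly(A)-selected libraries, and a rise in polyadenylated histone transcripts alone could give that. No library without poly(A) selection was analysed here, so this remained open.

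Long non-coding RNA genes were lower at 6 h than in quiescent cells (median -0.22, interval -0.26 to -0.19). Protein-coding sets matched on expression had a median of -0.17 (-0.21 to -0.14); only 0.55% were as low, which by the rule written beforehand would reject low expression, but that rule ignored the spread of the long non-coding median itself. With both sides resampled the difference was -0.049 (-0.10 to 0.0061), so low expression stayed open as an explanation. After a trend on GC content, exon length and mean expression was removed the classes differed by -0.16 (-0.20 to -0.13). Against coding sets matched on GC content alone or exon length alone the differences were -0.22 (-0.26 to -0.18) and -0.21 (-0.25 to -0.17). Matched genes were drawn from bins, and the smallest exon-length bin held only 20 coding genes, against 609 for GC content. The interval for length may therefore be too narrow. These values argue against GC content as the whole cause, and less firmly against length. The trend follows means, and as expression-matched coding sets had a mean of 0.055, it does not settle low expression. The 656 genes that overlap no other gene had a median of -0.21 (-0.27 to -0.11), against -0.23 for the 2135 that do, which argues against reads from overlapping genes.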

How the results depend on the processing

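Counts of called genes stayed within 1.5 times the reported ones under every choice of scaling, filter, test, samples in the fit and robust estimation. They ran from 6279 (DESeq2) to 8045 (only the 2 groups compared) for quiescent against asynchronous cells, 9054 (stricter filter) to 11705 (library totals) at 3 h, 9823 (stricter filter) to 11800 (library totals) at 6 h and 7720 (DESeq2) to 8861 (library totals) for 6 h against 3 h. With an adjusted p below 0.01 they were 5250, 8468, 9760 and 6847. Asking for a change of at least 2-fold left 917, 2632, 3277 and 1632 genes, by construction a smaller set. With library totals, transient falls rose to 2836 genes, while late falls dropped to 576 and transient rises to 1215. That scaling lowers the 3 h libraries as a whole, and beyond this the cause was not tested. The correlation of the starvation change with the contrast of 6 h and 3 h, near 0 in simulation, was -0.213 with library totals and with the replicate block and -0.283 among genes of at least 10 CPM. For 3 h and 6 h against quiescent cells the shared libraries favour a negative sign by themselves, so its sign under these choices shows nothing.

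The gene lists depended on the set test more than on anything else. With an estimated correlation 0 lists were called in quiescent against asynchronous cells, 0 at 3 h, 0 at 6 h and 0 for 6 h against 3 h, with a lowest adjusted p of 0.0861, although 36 of the 144 had an unadjusted p under 0.05. The fry test called 106 in all, with 28 at 3 h, 29 at 6 h and 26 for 6 h against 3 h. The cause was not tested. With library totals 64 of the 67 called lists kept their call and 3 lost it.

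Leaving out 1 library at a time gave 5197 to 7625 called genes for quiescent against asynchronous cells, 8719 to 10611 at 3 h, 9985 to 11438 at 6 h and 7406 to 8582 for 6 h against 3 h, and 18 to 19, 16 to 20, 17 to 19 and 14 to 16 called lists. Transient rises ranged from 1475 to 1745, transient falls from 1380 to 1698, progressive rises from 1073 to 1429, progressive falls from 1093 to 1419, late rises from 894 to 1207 and late falls from 856 to 1128. The group left with a lone library was assumed to vary like the others. Of the 785 results for named genes, library totals kept 761, weakened 21, strengthened 2 and reversed 1, and DESeq2 kept 771 and weakened 13. The reversed one was RPS16 at 3 h (-0.015, adjusted p = 0.846), where the shift of all genes at that scaling was larger than the change.

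Replicate numbers were treated as names. Deviations from the group mean of libraries with the same number correlated from -0.073 to 0.070 between groups, and from -0.47 to 0.30 among well-expressed genes, with mixed signs. The -0.47 was between 3 h and 6 h cells and the 0.30 between asynchronous and 6 h cells. Differences shared between libraries of different groups were therefore not excluded. A block on the numbers as given could not remove such differences where they do not follow the numbers. A replicate block gave 6929, 10151, 11332 and 8628 called genes and 19, 18, 17 and 14 called lists, and kept 782 of the 785 named-gene results. Depth was alike in all libraries, and 12879 genes with reads were too low to be tested.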

Other observations

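The circadian clock list was called lower from 3 h to 6 h, with a median of -0.67, and 3 rose and 14 fell of 17 tested (camera adjusted p = 0.00261, and adjusted p = 0.140 with an estimated correlation). CRY1, a repressor of the clock, rose at 3 h (1.21 ± 0.054) and fell back by 6 h (-0.99 ± 0.053), PER2 fell likewise (-1.41 ± 0.11), and BMAL1, an activator of the clock, rose (1.14 ± 0.066). It was not called in quiescent against asynchronous cells (camera adjusted p = 0.710), at 3 h (camera adjusted p = 0.877) or at 6 h (camera adjusted p = 0.164). Interferon-stimulated genes were lower from 3 h to 6 h, with a median of -0.61, and 9 fell and 12 were not called of 21 tested (camera adjusted p = 0.00768, and adjusted p = 0.610 with an estimated correlation), with IFIT2 at -1.45 ± 0.21; the call was lost without 3 h replicate 1 (adjusted p = 0.0541). They were not called at 3 h (camera adjusted p = 0.278).

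Small nucleolar RNA host genes were lower from 3 h to 6 h at a median of -0.10, and 1 rose, 7 fell and 14 were not called of 22 tested (camera adjusted p = 0.0460, and adjusted p = 0.663 with an estimated correlation), with SNHG3 at -0.57 ± 0.061 and SNHG12 at -0.51 ± 0.08. That call was lost with library totals (0.106), and without asynchronous replicate 1 (0.062), asynchronous replicate 2 (0.0605), 3 h replicate 2 (0.208) or 6 h replicate 1 (0.0935). At 3 h the list was not called (camera adjusted p = 0.0854), though SNHG12 rose by 1.2 ± 0.083 and SNHG15 by 1.2 ± 0.084. MicroRNA processing factors were called in no comparison (camera adjusted p = 0.107, then 0.310, 0.367 and 0.722 for 3 h, 6 h and 6 h against 3 h). Among them AGO2, which carries microRNAs to their targets, rose from 90.5 ± 2.64 to 384 ± 32.6 CPM at 3 h (2.09 ± 0.064). Endoplasmic reticulum chaperones were called in none (camera adjusted p = 0.144, then 0.262, 0.914 and 0.340), with HERPUD1 at -0.83 ± 0.051 at 6 h. Mitochondrially encoded genes were called in none (camera adjusted p = 0.816, then 0.952, 0.986 and 0.931).

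In the first library at 6 h, 3.917% of reads had low alignment quality and 4.29% were ambiguous, the highest shares among the 8 libraries.

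A pair of hypotheses was tested, both chosen after the temporal classes were seen, and neither prediction held. Transcripts that fell back by 6 h, in part or in full, might carry more destabilising ATTTA motifs in their 3' untranslated regions. Among 1028 coding genes raised at least 2-fold at 3 h with such a region, 524 transient ones had 2.5 motifs per kb and 504 sustained ones 2.26, a difference of 0.24 (two-sided permutation test, p = 0.11, adjusted p = 0.11), and 0.19 after the trend on AT content was removed (p = 0.153, permutation). Longer genes might also be expected to rise later. Instead 908 protein-coding late genes had a median span of 30.5 kb, and 4160 protein-coding genes that rose transiently, progressively or at both times 35.3 kb, a difference of -4.80 kb (two-sided permutation test, p = 0.022, adjusted p = 0.044), opposite to the prediction. By class these medians were 40.2 kb for transient, 35.1 kb for progressive and 32.0 kb for genes up at both times, so late genes lay closest to the last, and the pooled difference depends on the mix of classes.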
